A study of Rattus norvegicus with 2 samples.

How the data were processed

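Microglia had been sorted by flow cytometry from the hippocampus of male rat embryos on gestational day 20 and captured in droplets for single-cell RNA sequencing, with 7 male embryos pooled in each of 2 libraries. One library came from embryos exposed before birth to dexamethasone, a synthetic glucocorticoid, and the other from controls. Per the submitters' processing notes, reads had been processed with Cell Ranger 7.0.0 against the Rnor_6.0 assembly. The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and barcode, held in sparse matrices with 32623 genes, and no cell annotation was used. The dexamethasone library held 4328 barcodes with 42611920 UMIs and the control library 8342 barcodes with 69940778 UMIs. Gene names were taken from the deposited feature tables, where 12 of the 487 list entries had no match by symbol and are not analysed here. The values of 1 list member are not reported here. No annotation of that assembly was used here, so no coordinates are given.

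Cells with at least 200 genes and at most 20% of UMIs from mitochondrially encoded genes were kept. Scrublet was run per library at an expected rate of 0.008 per 1000 barcodes. Its automatic threshold marked 1 of 4199 tested dexamethasone cells, which was removed, and 0 of 8044 control cells. A caller that marks under 0.5% of over 5000 cells has not worked, so doublets remain in the data. The filters left 4198 dexamethasone and 8044 control cells. Both libraries were clustered together in scanpy 1.11.5 from 2000 highly variable genes, 30 principal components and 15 neighbours, by the Leiden method at resolution 0.5, without integration. Cell classes came from markers fixed before the data were examined. The rule that applied the markers was set afterwards. A cluster took another class when at least 2 of that class's markers, and more than of microglia, were among its top 25 genes by fold over the other cells, counting genes with at least 50 CPM that at least 25% of its cells carried. A remaining cluster was called microglia-like when at least 10 microglia markers reached 0.6 of their median level over such clusters, and was otherwise left unnamed. Cycling was treated as a state and not as a class, although cycling genes led clusters 2 and 7, and values are also given without those clusters.

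Counts were summed over the cells of a class in each library and scaled to CPM by the total UMIs of those cells, and the log2 ratio of dexamethasone over control was taken. With 1 library per group there is no replicate and no test was made. Intervals are at the 95% level, exact Poisson for a CPM, exact Clopper-Pearson for a share and exact conditional binomial for a ratio, and cover counting error only. A difference between shares combines the bounds of both. A list member was measured with at least 20 UMIs over both libraries, and a library at 0 stood at a floor of 3 counts. For each of 19 gene lists, also fixed beforehand, the median log2 ratio was placed among 10000 random lists matched on mean CPM in 20 bins, as a description of these libraries, with a counting interval from 1000 Poisson draws. Genes were named by a fixed rule. Among genes with a symbol, at least 100 UMIs, at least 50 CPM in a library and the same direction in every microglia-like cluster with at least 100 cells of each library, the 12 highest and 12 lowest ratios were taken. From each list came the 2 members of highest mean CPM and the 2 of largest absolute ratio with at least 20 CPM in a library. Clone-type names were also set aside, a step added after the data were seen. Shares of cells were compared after thinning each microglia-like cell to 4200 UMIs, the 10th percentile of the shallower library rounded down to 100, and the unthinned values are given too.

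The procedures were tested on simulated data at the level of 10513 genes. In the simulated comparison of microglia-like cells, intervals held the true ratio for 95.6% of 10313 unchanged genes, for 97.0% of 67 genes at a log2 size of 0.5, for 95.5% of 67 at 1.0 and for 89.4% of 66 at 2.0. Of 20 unchanged lists, 19 lay within the central 95% of random lists, and 20 of 20 lists shifted by 0.3 lay above it. These counts were drawn with Poisson error alone around 1 profile, as the intervals assume, so such coverage was largely built in. They held no batch difference and no joint movement of list members, and a shift of 0.3 exceeds most list medians found. The tests check the calculation and do not show what a list percentile means in the real libraries. A first test of thinning used the G2/M list, gave 100% in every arm and was uninformative, so it was replaced by a test on Sall1. There, simulated cells of 9000 and 6000 UMIs from the same profile carried the gene in 83.3% and 70.0% of cells, and in 63.7% and 66.0% once thinned to 5000.

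Alternatives chosen before the data were examined covered stricter cell filters (at least 500 genes, at most 10% mitochondrial UMIs), no doublet removal, Leiden resolutions 0.3 and 1.0, a gate on at least 3 of 7 microglia markers, TMM factors from edgeR 4.0.16, median-of-ratios scaling, other totals, per-cell means, thinning and removal of cycling clusters. Alternatives chosen after seeing the data removed the expected share of doublets, counted the unnamed cluster as microglia-like, replaced the G2/M list by the cycling markers, and clustered without mitochondrial genes, ribosomal protein genes and genes with an absolute log2 ratio of at least 0.25, which left 22067 genes.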

Results

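The study asked how glucocorticoid exposure before birth affects the maturation of microglia, the resident macrophages of the brain, in the rat hippocampus. One library of sorted cells came from dexamethasone-exposed embryos and 1 from control embryos, each a pool of 7 males at gestational day 20. The dexamethasone library held 42611920 UMIs in 4328 barcodes and the control library 69940778 UMIs in 8342 barcodes. No replicate exists within either group, so every difference given here is between these 2 libraries, and a batch difference cannot be separated from the exposure. Both pools expressed Y-linked genes alike, with Eif2s3y at 106.3 CPM in the dexamethasone library and 105.6 CPM in the control, and the median log2 ratio of the sex check list was -0.015.

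Most cells of both libraries resembled microglia. Clusters 0, 1, 2, 3 and 7 were microglia-like and held 3210 of 4198 dexamethasone cells (76.5%, exact interval 75.2 to 77.7%) and 6152 of 8044 control cells (76.5%, 75.5 to 77.4%). These shares describe a flow sort, and they moved with the clustering, to a difference of 4.88 points at Leiden resolution 1.0. Cluster 0 was led by Tmem119, P2ry12 and P2ry13, cluster 1 by Mcm genes of DNA replication, cluster 2 by mitotic genes, cluster 3 by Spp1, Gpnmb and Csf1, and cluster 7 by histone genes and Top2a. Clusters 4 and 10 resembled border-associated macrophages, the macrophages of meninges and vessels, with Mrc1, F13a1 and Ms4a7 or with Ccl24, Clec10a and Cd163. Smaller clusters were neutrophil-like, erythroid-like, neuron-like and choroid-like. Cluster 6 stayed unnamed and held 5.10% of dexamethasone and 2.71% of control cells. Microglia-like cells had a median of 9237 UMIs in the dexamethasone library and 7961 in the control.

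In microglia-like cells, F13a1, which encodes the A subunit of coagulation factor XIII and also marks border-associated macrophages, had the highest ratio of the named genes. It stood at 91.0 CPM in the dexamethasone library (Poisson interval 87.7 to 94.3) and 8.89 CPM in the control (8.12 to 9.71), a log2 ratio of 3.35 (3.22 to 3.49). The ratio ranged from 2.01 in cluster 3 to 4.44 in cluster 1. After thinning to 4200 UMIs, 14.5% of 3055 dexamethasone cells and 2.07% of 5564 control cells carried an F13a1 UMI, with 155 and 588 shallower cells left out. Without thinning these shares were 20.8% and 3.59%. In neuron-like cells, taken as background, thinned shares were 0 of 68 dexamethasone cells (exact upper bound 5.28%) and 1.18% of 169 control cells, with 52 and 314 shallower cells left out. All 120 and 483 neuron-like cells had median depths of 5515 and 1739 UMIs. Cideb, of lipid droplet and lipoprotein handling, stood at 74.2 against 25.3 CPM. Plac8 stood at 286.1 against 139.2 CPM, and Tspo, which encodes an outer mitochondrial membrane protein widely used as a marker of reactive microglia, at 577.6 against 312.2 CPM. Cpxm1 had a log2 ratio of 0.91 and Grcc10 one of 0.99. The ribosomal protein genes Rps19l2, Rpl30 and Rpl37 had log2 ratios of 1.75, 1.21 and 1.14. Ppial4d at 1.37, Sumo4 at 1.03 and H2aj at 1.04 completed the 12 highest. Rps19l2, Ppial4d and Sumo4 have close copies in the genome, so their counts are uncertain.

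**Figure D1:**
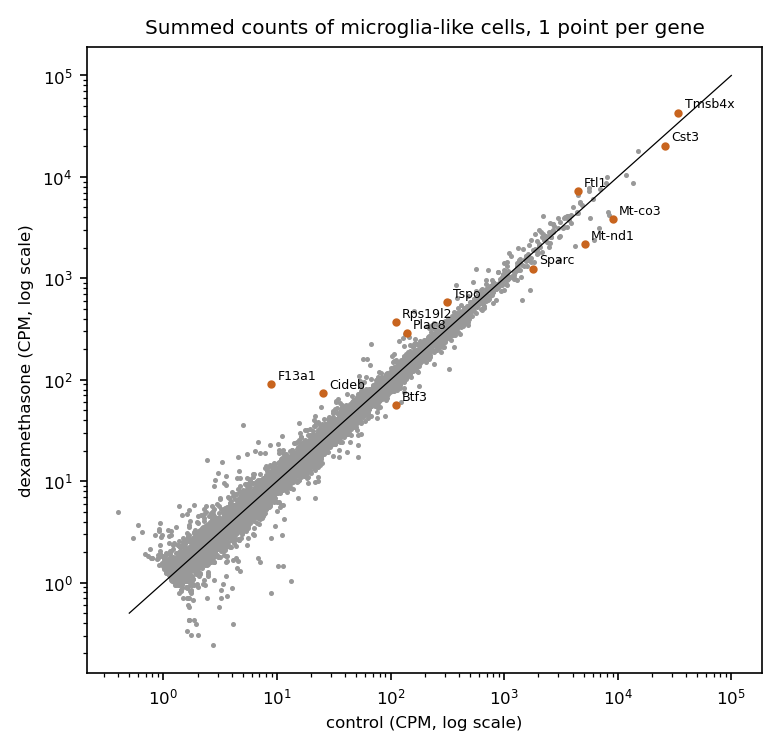
CPM of each gene with at least 100 UMIs in microglia-like cells, control on the x axis and dexamethasone on the y axis, both on log scales, with the line of equal CPM and labelled genes in orange. F13a1 lies above the line at 8.89 against 91.0 CPM, and Mt-co3 below it at 9044 against 3847 CPM.

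Mitochondrially encoded transcripts were lower in the dexamethasone library. They made up 3.11% of UMIs in microglia-like cells of the dexamethasone library and 5.98% in the control, a log2 ratio of -0.94 (-0.95 to -0.94), and 12 of 13 measured genes were lower. The exception, Mt-atp8, stood at 165.1 against 135.7 CPM. Mt-co3, a subunit of cytochrome c oxidase, stood at 3847 against 9044 CPM, and Mt-nd1, a subunit of complex I, at 2166 against 5104 CPM. Mt-nd4l had the lowest log2 ratio, -1.34. Mt-atp6, Mt-nd6, Mt-nd4, Mt-co1, Mt-nd2 and Mt-cyb were also among the 12 lowest, with Mt-cyb at -0.87. Nuclear genes of oxidative phosphorylation had a median log2 ratio of -0.015, with 14 of 32 members higher and 18 lower. The mitochondrial share was lower in every other class compared too: 3.52% against 6.37% in border-associated-macrophage-like, 2.04% against 4.88% in neuron-like and 2.72% against 4.48% in neutrophil-like cells. Ribosomal protein genes together were higher in microglia-like cells, 16.5% against 14.4% of UMIs. Their log2 ratio was also above 0 in border-associated-macrophage-like (0.20), erythroid-like (0.36), unnamed (0.11) and neuron-like cells (0.035), and below 0 in neutrophil-like cells (-0.13). The haemoglobin genes Hba-a1 and Hba-a2, of red cells, stood at 87.7 against 176.7 CPM and 44.3 against 90.2 CPM. Their direction turned when cells were clustered without genes that differ between the libraries. Haemoglobin genes together were lower in border-associated-macrophage-like, neutrophil-like and unnamed cells too, with log2 ratios of -1.17, -0.82 and -1.40. The ratio was -0.15 in erythroid-like cells and 3.72 in neuron-like cells, where 1 of 120 dexamethasone cells held 90% of those UMIs. The transcription factor gene Btf3 completed the 12 lowest, at 56.2 against 111.0 CPM.

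Genes of mature, homeostatic microglia were lower on balance in the dexamethasone library. Of 22 measured members 17 were lower and 5 higher, and the counting interval lay below 0 for 12 and above 0 for 4. The median log2 ratio was -0.098 (-0.16 to -0.076), at percentile 2.45 of random lists, and it was -0.063 with members of at least 100 UMIs and -0.15 by per-cell means. In neuron-like and neutrophil-like cells, which should lack these genes, the median lay lower still, at -0.53 and -0.43, while it was -0.051 in border-associated-macrophage-like, 0.080 in erythroid-like and 0.026 in unnamed cells. Cst3, encoding the protease inhibitor cystatin C, stood at 20382 against 26177 CPM, and Sparc, a matricellular protein, at 1247 against 1787 CPM. Csf1r, the receptor on which microglia depend for survival, was slightly higher, at 1719 against 1605 CPM. Chosen after their values were seen, the purinergic receptor P2ry12 had a log2 ratio of -0.31 and Tmem119 one of -0.30. Cluster 0, which these genes lead, held 912 of the 3210 dexamethasone and 2396 of the 6152 control microglia-like cells. Within clusters P2ry12 ranged from -0.19 in cluster 0 to -0.36 in cluster 2 and Tmem119 from -0.089 in cluster 7 to -0.33 in cluster 3, and the interval included 0 only for Tmem119 in clusters 2 and 7. Within clusters the list median was -0.074 in cluster 0, -0.12 in cluster 1, -0.13 in cluster 2, -0.033 in cluster 3 and -0.010 in cluster 7, and only in cluster 7 did the counting interval include 0.

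Genes listed for immature or embryonic microglia were higher on balance in the pooled cells, with 12 of 20 higher and 8 lower. The median log2 ratio was 0.20 (0.15 to 0.23), at percentile 99.99, and it was 0.14 with the marker gate. The highest members were F13a1 and Ftl1, a ferritin light chain, at 7298 against 4442 CPM, and the most abundant was Tmsb4x, an actin-binding peptide, at 43011 against 34217 CPM. The pooled median was not repeated within clusters, where it was -0.074, 0.036, 0.088, 0.15 and -0.11 in clusters 0, 1, 2, 3 and 7. Only in cluster 3 did the counting interval exclude 0.

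The glucocorticoid receptor response list, which asks whether exposure left a transcript signature at sampling, did not stand apart. Of 23 members 10 were higher and 13 lower, with a median log2 ratio of -0.030 (-0.086 to 0.039) at percentile 29.3, and alternatives ran from -0.074 to 0.021. Fkbp5, a chaperone induced by the receptor, stood at 25.4 against 32.4 CPM, a log2 ratio of -0.35 (-0.47 to -0.23). Dusp1, a phosphatase of MAP kinases, was higher at 27.8 against 11.1 CPM, and it also belongs to the immediate-early list. Cebpb at 277.3 against 238.7 CPM, Mt1 at 145.4 against 113.5 CPM and Ucp2 at 357.6 against 349.4 CPM were the other named members, and the log2 ratio of Ucp2 turned to -0.016 after thinning. Genes of steroid receptors and glucocorticoid metabolism had a median of 0.061, with Hsp90ab1 at 2582 against 3030 CPM.

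In the pooled microglia-like cells mitotic genes were lower on balance and replication genes slightly higher. Of 51 members of the G2/M list 47 were lower, with a median log2 ratio of -0.23 (-0.27 to -0.19), and none of the 10000 random lists lay lower. Cenpe, a kinetochore motor, stood at 54.1 against 81.1 CPM and Ckap2l at 16.4 against 23.6 CPM. The median was 0.007 without clusters 2 and 7, but within clusters 0, 1, 2, 3 and 7 it was -0.15, -0.30, -0.084, -0.076 and -0.10, with only the counting interval of cluster 3 including 0. The per-cell means gave -0.15. Of 40 S phase members 25 were higher, with a median of 0.076 (0.048 to 0.14) at percentile 98.7, and the helicase subunit Mcm2 stood at 47.3 against 33.4 CPM. Rrm2, of the largest absolute ratio by the naming rule, was lower, at 15.1 against 22.1 CPM. The S phase median was not repeated within clusters, where it was 0.13, -0.15, -0.071, 0.016 and -0.020 in the same order, and in cluster 1 the interval lay below 0 and 32 of 40 members were lower. Cluster 1 held 973 of the 3210 dexamethasone and 1187 of the 6152 control microglia-like cells. Clusters 2 and 7, led by cycling genes, held 370 and 316 of these dexamethasone cells and 854 and 641 of these control cells. Their smaller part in the dexamethasone library enters the pooled G2/M median, and members of that list move together with it. The place of that median among random lists is therefore a description only. The planned share of thinned cells with at least 3 UMIs of the G2/M list was 80.6% in the dexamethasone library (79.1 to 82.0%) and 81.0% in the control (80.0 to 82.0%), and 94.8% and 92.5% without thinning. This share does not measure cycling here, since thinned neuron-like cells reached 97.1% and 94.1%, while thinned erythroid-like cells reached 8.91% and 12.3%. The most abundant members, Hmgb2 and Jpt1, had log2 ratios of -0.043 and -0.049, which turned to 0.017 and 0.011 after thinning and to 0.16 and 0.022 without clusters 2 and 7. Hmgb2 turned also with the marker gate, to 0.027, and by per-cell means, to 0.013. With the cycling markers in its place, chosen after seeing the data, the shares were 22.6% and 24.3%, a difference of -1.78 points (-3.65 to 0.11), against 13.2% and 10.1% in neuron-like and 3.96% and 6.92% in erythroid-like cells.

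**Figure D2:**
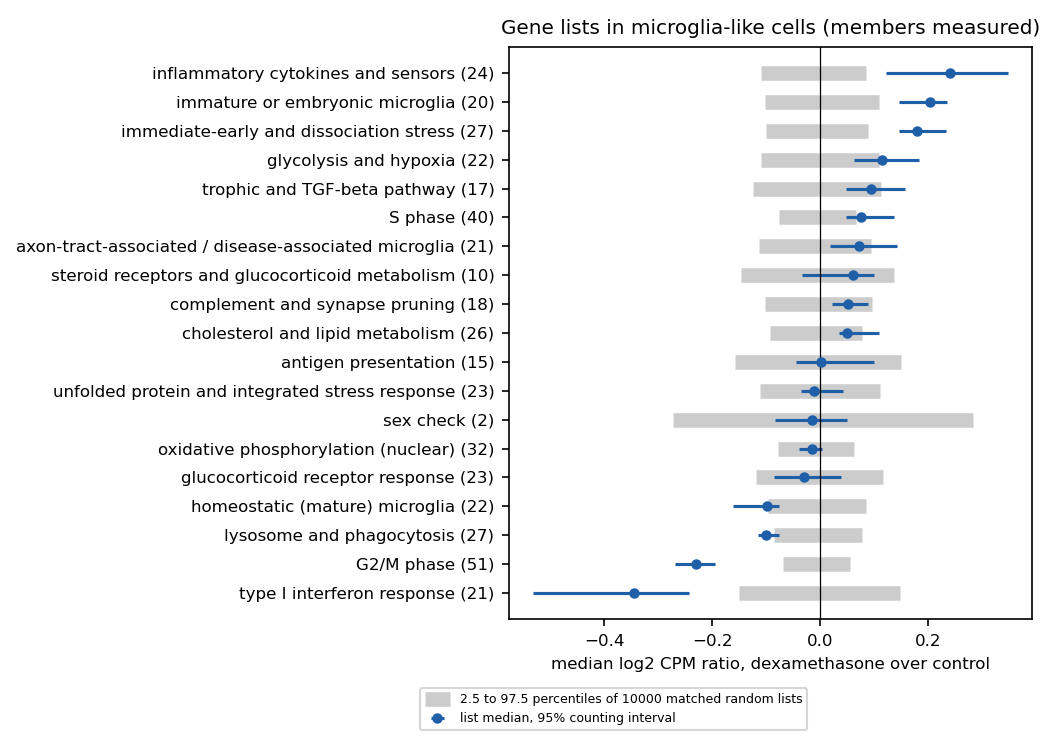
Median log2 CPM ratio of dexamethasone over control on the x axis for each gene list in microglia-like cells, with the number of measured members in brackets. Points with bars are medians with 95% counting intervals and grey bands are the central 95% of 10000 matched random lists. The G2/M list at -0.23 and the interferon list at -0.34 lie below their bands.

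Genes of the inflammatory cytokines and sensors list and immediate-early genes were higher on balance, and interferon-response genes lower, in the dexamethasone library. Of 24 members of the inflammatory cytokines and sensors list 19 were higher, with a median log2 ratio of 0.24 (0.12 to 0.35), above all random lists, and 0.15 with members of at least 100 UMIs only. The chemokine gene Ccl12 stood at 37.4 against 15.6 CPM, Ccl2 at 84.7 against 55.3 CPM and Ccl3 at 169.5 against 130.7 CPM, while the lipopolysaccharide co-receptor Cd14 had a log2 ratio of -0.061, which turned to 0.032 by per-cell means. Chosen after their values were seen, Cxcl10 and Cxcl16 had log2 ratios of 0.17 and 0.017 with intervals that include 0. In the immediate-early and dissociation stress list 22 of 27 members were higher, with a median of 0.18 (0.15 to 0.23), and the transcription factor Egr1 stood at 40.2 against 21.3 CPM. Of the most abundant members, Hspa8 did not differ beyond counting error, with a log2 ratio of 0.015 (-0.011 to 0.04). Dnaja1 was slightly lower, at -0.061 (-0.10 to -0.02). Genes of this list respond to tissue dissociation. Of 21 type I interferon response members 17 were lower, with a median of -0.34 (-0.53 to -0.24). Rtp4, an interferon-induced gene, had a log2 ratio of -0.73 (-0.89 to -0.57). The abundant members Bst2 and Ifi47 lay near equality, with log2 ratios of -0.037 and 0.072, and Bst2 turned to 0.017 with stricter filters. Within cluster 7 the list median was -0.019. In border-associated-macrophage-like cells the inflammatory, immediate-early and interferon medians were 0.15, 0.22 and -0.22, with intervals that exclude 0. Within cluster 4 of that class the medians were 0.039, 0.17 and -0.23, and only the immediate-early interval excluded 0. In the same order they were 0.018, 0.225 and -0.27 in erythroid-like cells and -0.50, -0.059 and -0.61 in neuron-like cells. They were 0.087, 0.066 and 0.063 in neutrophil-like cells and -0.014, 0.087 and 0.048 in unnamed cells. The shifts were thus shared in part by other classes.

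Members of the complement and synapse pruning list went both ways, with 10 of 18 higher and a median of 0.052 that turned to -0.005 after thinning. The C1q genes, which encode the recognition molecule of the classical complement pathway, were higher, with C1qa at 7833 against 5583 CPM, C1qb at 10044 against 7983 CPM and C1qc at 6584 against 4452 CPM. Together these genes were also higher in erythroid-like cells, at 1877 against 1046 CPM, and lower in neuron-like cells, at 3612 against 4133 CPM. In border-associated-macrophage-like, neutrophil-like and unnamed cells they were higher, with log2 ratios of 0.33, 0.29 and 0.79, so 4 of 5 other classes went the same way. Erythroid-like, neutrophil-like and unnamed cells held less C1q than microglia-like cells, which stood at 24461 against 18019 CPM. Free RNA and remaining doublets were not tested for C1q, so these classes are not independent repeats. Itgam, a chain of complement receptor 3, had a log2 ratio of -0.54. In the lysosome and phagocytosis list 20 of 27 members were lower, with a median of -0.10 at percentile 1.11, including the protease Lgmn at 2250 against 2501 CPM, while the Fc receptor Fcgr2b was higher at 73.0 against 41.2 CPM. The median of this list was lower still in neuron-like cells, at -0.75 with 25 of 26 members lower. It was -0.052 in border-associated-macrophage-like, -0.068 in neutrophil-like, 0.21 in erythroid-like and 0.14 in unnamed cells. Within cluster 4 of the border-associated-macrophage-like cells it was -0.18, with 23 of 27 members lower. The antigen presentation median was 0.001, with B2m at 6030 against 6026 CPM. The class I gene RT1-A2, of a family with close copies, stood at 926.3 against 529.8 CPM, and its counts are uncertain. Medians were 0.071 for axon-tract-associated and disease-associated genes, 0.049 for cholesterol and lipid metabolism, 0.12 for glycolysis and hypoxia, -0.011 for the unfolded protein and integrated stress response and 0.094 for the trophic and TGF-beta pathway.

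**Figure D3:**
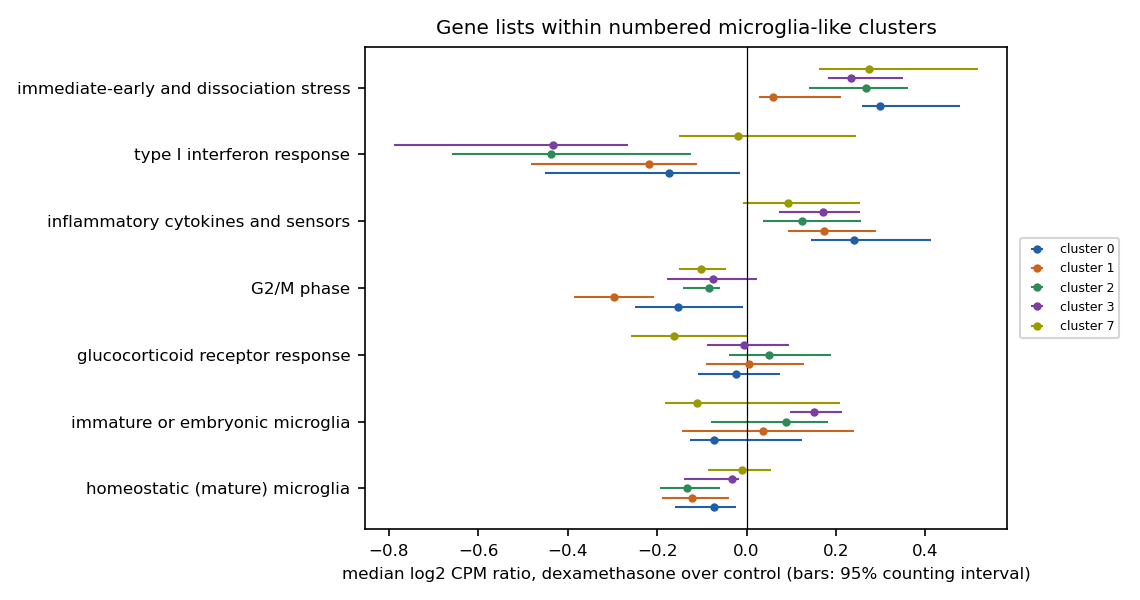
Median log2 CPM ratio of dexamethasone over control on the x axis for 7 gene lists within each numbered microglia-like cluster, with 95% counting intervals as bars. Inflammatory and immediate-early medians lay above 0 in all 5 clusters, although the interval of the inflammatory list in cluster 7 (-0.009 to 0.25) includes 0, and the immature list ranged from -0.11 to 0.15.

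When cells were clustered without mitochondrial, ribosomal protein and library-different genes, as chosen after seeing the data, the cluster led by Tmem119, P2ry12 and P2ry13 held 18.1% of dexamethasone cells (17.0 to 19.3%) and 24.6% of control cells (23.7 to 25.6%). At the finer resolution of 1.0 the corresponding cluster held 13.1% and 19.2%. A cluster led by Mcm genes held 14.8% and 12.1%, and the cluster led by Spp1, Gpnmb and Csf1 held 14.96% and 14.87%. The last pair lay within counting error. A microglia-like cluster led by Cxcl17, Cd14 and Clec2l held 15.7% and 12.6%, and an unnamed cluster led by Pf4, Mt1 and Grcc10 held 9.24% and 6.42%.

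In border-associated-macrophage-like cells, of which cluster 4 held 433 dexamethasone and 741 control cells and cluster 10 held 13 and 147, the glucocorticoid receptor response list had a median of -0.42, with 16 of 19 members lower. Within cluster 4 alone it was -0.40, with 13 of 18 lower. Among members chosen after their values were seen, Fkbp5 stood at 11.3 against 28.7 CPM, the NF-kappaB inhibitor Nfkbia at 30.1 against 51.3 CPM and the mTOR inhibitor Ddit4 at 6.74 against 15.9 CPM in the whole class. These genes were picked from the lower members of the list. Their class sums mix clusters 4 and 10, which make up unlike parts of the class in the 2 libraries. F13a1 stood at 926.4 against 199.5 CPM in cluster 4 and at 2761 against 2534 CPM in cluster 10. It was also higher in neutrophil-like cells, at 282.6 against 79.1 CPM, while in the unnamed cluster, at 62.6 against 86.0 CPM, the interval of the log2 ratio (-0.98 to 0.071) includes 0. That cluster is not matched in depth, with medians of 5080 and 1554 UMIs. In neuron-like cells the glucocorticoid receptor response list went the other way, with a median of 0.42 (0.082 to 0.58) and 12 of 16 members higher. The G2/M median was likewise higher there, at 0.50, and in neutrophil-like cells, at 0.84. The neuron-like class is not matched between the libraries either: its median depth was 5515 against 1739 UMIs, and at resolution 1.0 it split into a deep cluster of 37 dexamethasone and 105 control cells and a shallow one of 86 and 430.

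**Figure D4:**
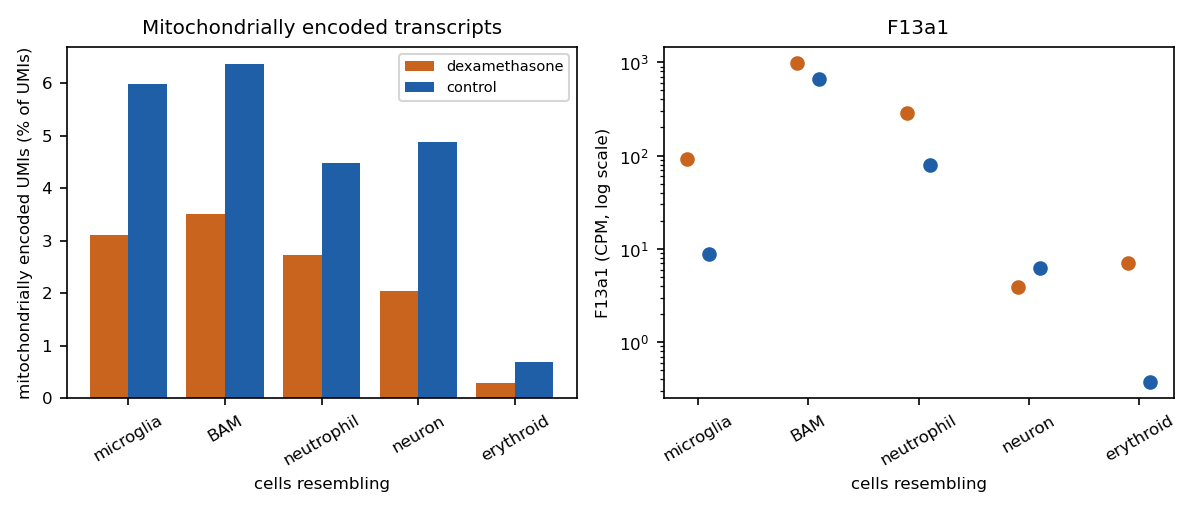
Mitochondrially encoded UMIs as a percent of all UMIs (left, bars) and F13a1 in CPM on a log scale (right, points) by cell class, with dexamethasone in orange and control in blue, and BAM for border-associated-macrophage-like cells. The mitochondrial share was lower in the dexamethasone library in every class drawn, while F13a1 in neuron-like cells stood at 3.90 against 6.19 CPM.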

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

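The tests on F13a1, the tests of mitochondrial transcripts across classes, and the test on leading genes of the dexamethasone-rich cluster were chosen only after the results were seen. The test on the 10th percentile of the mitochondrial share and the clustering at the finer resolution were set before their results were seen.

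Outside the comparisons of the report, the embryonic globin gene Hbe1 reached 9553 CPM in erythroid-like cells of the dexamethasone library against 4.43 CPM in the control. This signal came from few cells, since 4 of 102 held 90% of its UMIs. Haemoglobin genes reached 6312 CPM in neuron-like cells of the dexamethasone library against 478.1 CPM in the control, and 1 of 120 cells held 90% of those UMIs.

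Mitochondrially encoded transcripts were lower in the dexamethasone library. A difference of microglia-like cells alone is argued against by a median log2 ratio of -0.93 over the other classes. A tail of damaged control cells is argued against as well, since the 10th percentile of the mitochondrial share, 1.54% against 3.85%, already differed by -1.32 on the log2 scale. The highest ratio among the other classes was -0.72, as a difference of the whole library would give. Handling, batch or an exposure that reached all cells stay open, and with 1 library per group they were not separated.

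F13a1 was higher in microglia-like cells of the dexamethasone library. Free RNA is argued against, because the upper bound in neuron-like cells of that library was 11.39 CPM against 91.0 CPM, although erythroid-like cells held 7.05 CPM against 0.37 CPM on 1 control UMI. Cells of cluster 4 mixed into the class would need a share of 8.86% to bring the whole excess. They would bring Ms4a7 to 26.5 CPM and Stab1 to 23.4 CPM, where 14.3 and 17.9 CPM were found. The median log2 ratio of the other 10 macrophage markers was -0.081. That median decides nothing on cluster 4 cells, since Clec10a, Ccl24 and Cd163, at most 1.51 CPM and leading cluster 10, pull it down. Mrc1, Pf4, Ms4a7 and Stab1 were higher and Lyve1, Folr2 and Dab2 lower, each beyond counting error. A counting difference of the gene stays open. The upper bound of 0.28 in cluster 10 and the ratio of 2.22 in cluster 4 decide nothing, as F13a1 helps to define both clusters. The ratio of 1.84 in neutrophil-like cells fits it, while unnamed cells, not matched in depth, had a ratio of -0.46 (-0.98 to 0.071). Ratios were uneven, from 2.01 (1.66 to 2.37) in cluster 3 to 4.44 (4.11 to 4.80) in cluster 1. The microglia-like clusters come from the same clustering, and F13a1 led a microglia-like cluster under the stricter filters. The assignment of cells can therefore make the ratios uneven, and they do not decide the question either. A smaller share of cluster 4 cells, for Ms4a7 and Stab1 each had a log2 ratio of 0.42, a response to dexamethasone and a difference between the pools of embryos or batches also stay open, untested.

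At resolution 1.0, a microglia-like cluster of 1120 dexamethasone and 299 control cells appeared, led by Rps19l2, Cideb, Rpl37 and Rpl30. Under the stricter filters a more uneven one held 1019 and 32 cells, led by F13a1, Cideb, Rps19l2 and Rgs1, with 1 border-associated macrophage marker and 0 microglia markers among its 10 leading genes. The leading genes of the first cluster had a median log2 ratio of 1.11 in border-associated-macrophage-like cells, so they differed between the libraries in another class too. Without genes that differ between the libraries, no microglia-like cluster of at least 100 cells held more than 40.08% dexamethasone cells, but removing those genes builds in that outcome, so it decides nothing, and an unnamed cluster led by Mt1, Fabp3 and Grcc10 still held 57.61%. A distinct state of microglia and a difference between the libraries both stay open.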

How the results depend on the processing

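The alternatives with doublets at the expected share removed, the unnamed cluster added, the cycling markers and the clustering without library-different genes were chosen after seeing the data. No paired analysis was possible because each group has 1 library. Of the 24 genes named by extreme ratio, 22 kept their sign under every alternative, and Hba-a1 and Hba-a2 were 0.21 and 0.072 when clustered without library-different genes. The naming rule required extreme ratios with the same direction across clusters of the same cells. Kept signs were thus largely built in and give no support. The microglia-like share difference of -0.014 points moved to 2.89 with stricter filters, whose microglia-like cells include a cluster of 1019 dexamethasone and 32 control cells without a leading microglia marker, -2.29 with no doublet removal, which returned 1 cell, 2.09 at resolution 0.3, 4.88 at resolution 1.0 and 2.37 with the unnamed cluster, so no direction is given. The cycling share difference of -0.43 points was 2.29 without thinning and 3.89 with the S phase list. The homeostatic median of -0.098 was -0.072 with the marker gate and -0.063 with members of at least 100 UMIs, and the immature median of 0.20 was 0.14 with the gate. The G2/M median of -0.23 was -0.32 with stricter filters, -0.30 at resolution 1.0, -0.15 by per-cell means and 0.007 without the clusters led by cycling markers. That alternative leaves out the cells richest in these genes, yet within the remaining clusters 0, 1 and 3 the medians were -0.15, -0.30 and -0.076. The mix of these clusters differed, with 912, 973 and 639 dexamethasone cells and 2396, 1187 and 1074 control cells. A pooled median can depart from the medians within clusters through such a mix, and its part in the 0.007 was not computed. The inflammatory median of 0.24 was 0.15 with members of at least 100 UMIs. The complement median of 0.052 was -0.005 after thinning. Of the other genes named in the text, Bst2 was 0.017 with stricter filters, Cd14 0.032 by per-cell means, Mrc1 -0.043 with the gate in place of 0.24 and Ucp2 -0.016 after thinning. Hmgb2 was 0.027 with the gate, 0.013 by per-cell means, 0.017 after thinning and 0.16 without cycling clusters, and Jpt1 was 0.011 after thinning and 0.022 without cycling clusters. For all of these the cause was not tested. Of 1498 gene values under alternatives, 1237 lay within the main counting interval, 249 lay outside with the same sign and 12 changed sign. The scaling alternatives moved the median of all genes only between -0.019 and 0.002. Neutrophil-like and erythroid-like classes, with 100 and 102 dexamethasone cells, limit what depth can show there.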

Other observations

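Among nuclear genes outside the ribosomal and haemoglobin groups, chosen after their values were seen, the cytoskeletal genes Tuba1a and Actb were lower in microglia-like cells of the dexamethasone library, at 142.4 against 240.4 CPM and 3950 against 5660 CPM. Transcripts of neurons, in which Tuba1a is abundant, were lower in the same cells too, with log2 ratios of -1.16 for Dcx, -1.97 for Cd24, -2.17 for Tubb3, -2.81 for Stmn2 and -3.15 for Elavl2, and neuron-like cells were 120 of 4198 dexamethasone and 483 of 8044 control cells. The lipid transfer gene Pltp stood at 279.5 against 408.9 CPM and the stress gene Herpud1 at 52.1 against 77.0 CPM. Rgs1, a regulator of G protein signalling, was higher at 60.7 against 32.8 CPM.

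Across genes, log2 ratios in microglia-like cells correlated with those in border-associated-macrophage-like cells at r = 0.64 over 7078 genes, in erythroid-like cells at 0.58 over 692 genes, in unnamed cells at 0.51 over 2101 genes, in neutrophil-like cells at 0.50 over 3199 genes and in neuron-like cells at 0.27 over 3766 genes. Genes are not independent replicates. Each r rests on its own set of genes, those with at least 100 UMIs in both classes, and counts were not matched. The r values therefore do not rank the classes by likeness.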
